A study of Arabidopsis thaliana with 24 samples.

How the data were processed

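Root transcripts were measured by RNA-seq in 24 libraries of *Arabidopsis thaliana*, 3 in each of 8 groups given by genotype, treatment and day. The libraries were stranded mRNA libraries per the labels. Per the submitters' processing notes, reads were checked with FastQC and aligned to TAIR10 with TopHat2 2.0.11, Bowtie 1.1.0 and SAMtools 0.1.18. Per the file headers, the authors counted reads over exons per gene with featureCounts 1.4.3-p1 at 4 dpi and 1.4.6 at 10 dpi, so the unit of these files is the read count, not normalized. The counting commands took no strand option, no multi-mapping reads and no reads over more than 1 gene, so a gene's count may include antisense reads, and reads over bases shared by genes are lost. Of 33602 genes, 4118 share exon bases with another gene. The different counting versions and sequencing sets of the days were another reason to fit each day alone. The authors' deposited tables cover 6 comparisons and give an adjusted p-value, a log2 fold change and mean CPM per group. Per the submitters' processing notes they came from edgeR 3.0. They list genes with an adjusted p-value below 0.05.

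Gene symbols came from an annotation table of TAIR10.1, which was used for names alone. It matched 32835 of the 33602 identifiers and gave a symbol for 10654. Coordinates are those of the count files (TAIR10). Library totals were 7064472 to 11103291 counts at 4 dpi and 7019363 to 10589909 at 10 dpi, and the 10 most abundant genes took 3.13 to 4.54% of a library. All 24 libraries were used, and no sample was left out.

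Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by group with filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and fitted with the robust quasi-likelihood model. The 12 libraries of a day were fitted together as 4 groups. The comparisons were infection in each genotype, genotype in each treatment and the interaction, on each day, and the difference of WT infection between days, fitted on the 12 WT libraries, which makes 11 in all. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, and genes passed at an adjusted p of 0.05. All tests of differences were two-sided. These p-values measure the spread between these samples, which may be partly technical. Log2 differences are those of the fit with edgeR's default prior count and are given ± SE. The SE is the absolute log2 difference divided by the square root of the F statistic. A prior count of 2 was used for log2 CPM alone. CPM values use the TMM factors. Folds against a group at 0 counts used a floor of 3 counts over the group, and those against 1 to 3 counts have a 95% counting interval. Intervals and floors cover counting error only. With 3 libraries against 3, an exact permutation test of a single gene could not go below 0.1.

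In each comparison the genes named were, among those past the threshold with a symbol, an average log2 CPM above 1 and no overlap between the groups, the 8 with the largest rise and the 8 with the largest fall. Added to these were the 10 type-A ARR genes and, from each list described, up to 4 members with the smallest adjusted p. For interactions and the difference between days, the 5 largest of each sign past the threshold were taken. From these a smaller number is named in the text. This rule, the tests, the alternatives and 32 gene lists with 496 genes were fixed before the data were examined. Lists of heat shock and nitrate response genes, 20 genes each, were added after such genes were seen to change. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. The alternatives for lists were an estimated correlation, a replicate block and fry, whose directional test asks whether the genes move 1 way on balance and whose mixed test asks whether they change in either direction. Lists were also adjusted over the list alone.

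The alternatives for genes were median-ratio and upper-quartile factors, no filter on low counts, a filter of CPM above 1 in at least 3 libraries, a replicate block, DESeq2 1.42.0, a fit of the compared libraries alone, a fit of all 24 libraries and leaving out each library in turn. Limma's voom with library quality weights, fits without the infected mutant libraries, thinning to the smallest library and leaving out genes within 500 kb of shared large genotype differences were added after the data were seen. Overlaps of lists of genes were tested with one-sided Fisher's exact tests. The overlap of genotype and infection effects, which share control libraries, was compared with 20 simulations in which neither had an effect. Positions were compared with 1000 random draws of as many tested genes, with GenomicRanges 1.54.1 for overlapping exons. Intervals of the median share of WT level in a mutant library came from resampling the genes and do not cover spread between samples.

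The fit was tested on simulated data made from the real libraries, with 200 genes changed in each of 4 comparisons. Of genes changed by a log2 of 2, 94 to 97% were recovered, and of those changed by 1, 51% in WT infection at 4 dpi and 60 to 68% in the others. False calls made up 2.67 to 7.23% of calls. All simulated libraries of a day had the same spread per gene, and the 4 comparisons were WT infection and genotype in control roots on each day. These shares therefore do not cover comparisons with the infected mutant libraries, which spread more widely.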

Results

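RNA-seq read counts were collected from *Arabidopsis thaliana* roots of the wild type Col-0 (WT) and of arrOct, a mutant with lesions in the type-A response regulator genes ARR3, ARR4, ARR5, ARR6, ARR7, ARR8, ARR9 and ARR15. Type-A response regulators are induced by cytokinin and damp its signalling. Roots were left uninfected (control) or infected with the beet cyst nematode *Heterodera schachtii*, whose juveniles turn root vascular cells into a feeding site called a syncytium. Roots were sampled at 4 and 10 days post infection (dpi). The 24 libraries fell into 8 groups of 3. Between 7019363 and 11103291 reads per library were assigned to genes, and between 21084 and 23138 genes had at least 1 read. The 21084 were those of infected mutant replicate 3 at 4 dpi, and every other library had at least 22449. Levels below are means in counts per 1e6 reads (CPM) ± SD over 3 libraries. Infected mutant libraries stood apart: their mean correlation with the other libraries of their group was 0.923 to 0.947 at 4 dpi and 0.936 to 0.953 at 10 dpi, against 0.98 to 0.989 in the other groups. They included the library with the fewest reads at 4 dpi (7.06 M), and at 10 dpi all 3 (7.02 to 7.46 M) held fewer reads than any other library of that day. Of the genes named below, ADH1, CASP1, CHS, CKX5, CYP81F4, GRF3, KCS2, PER64, RPP8, SADHU1-1, SGN3, SRO4, WRKY33, AT2G43550 and AT3G05770 share exon bases with another annotated gene, so their unstranded counts are uncertain. The same holds for close paralogs such as LHCB1.1 and LHCB1.2, PP2-A6 and PP2-A8, and the small heat shock genes.

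The targeted genes were read in every library first, because they check the genotype labels. ARR3 (AT1G59940, chromosome 1, 22065617 to 22066973, TAIR10) lay at 5.03 to 24.2 CPM in the 12 WT libraries and at 0 to 0.815 CPM in the 12 mutant libraries. ARR4 (AT1G10470) lay at 76.6 to 124 CPM in WT and 3.41 to 11.3 CPM in the mutant. ARR6 (AT5G62920) had group means of 17.3 to 34.9 CPM in WT and lay at 0.535 to 4.38 CPM in the mutant libraries, and ARR8 (AT2G41310) lay at 35.5 to 59.9 CPM in WT and 2.63 to 8.56 CPM in the mutant. These 4 genes separated the genotypes in all 24 libraries. The highest ARR3 value of a mutant library, 0.815 CPM, came from infected replicate 1 at 10 dpi, while the other 5 mutant libraries of that day held 0 CPM. ARR7 (AT1G19050) spanned 7.66 to 23.7 CPM in WT and 1.9 to 7.69 CPM in the mutant. ARR9 (AT3G57040), at 29.8 to 39.3 and 10.2 to 34 CPM, and ARR5 (AT3G48100), at 20.2 to 42.9 and 25.7 to 57.7 CPM, overlapped between genotypes. ARR15 (AT1G74890) was higher in the mutant, at 3.98 to 9.49 CPM against 0.55 to 1.6 CPM in WT. Reads outside an insertion do not test whether a gene works, so ARR5, ARR9 and ARR15 check nothing here.

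**Figure D1:**
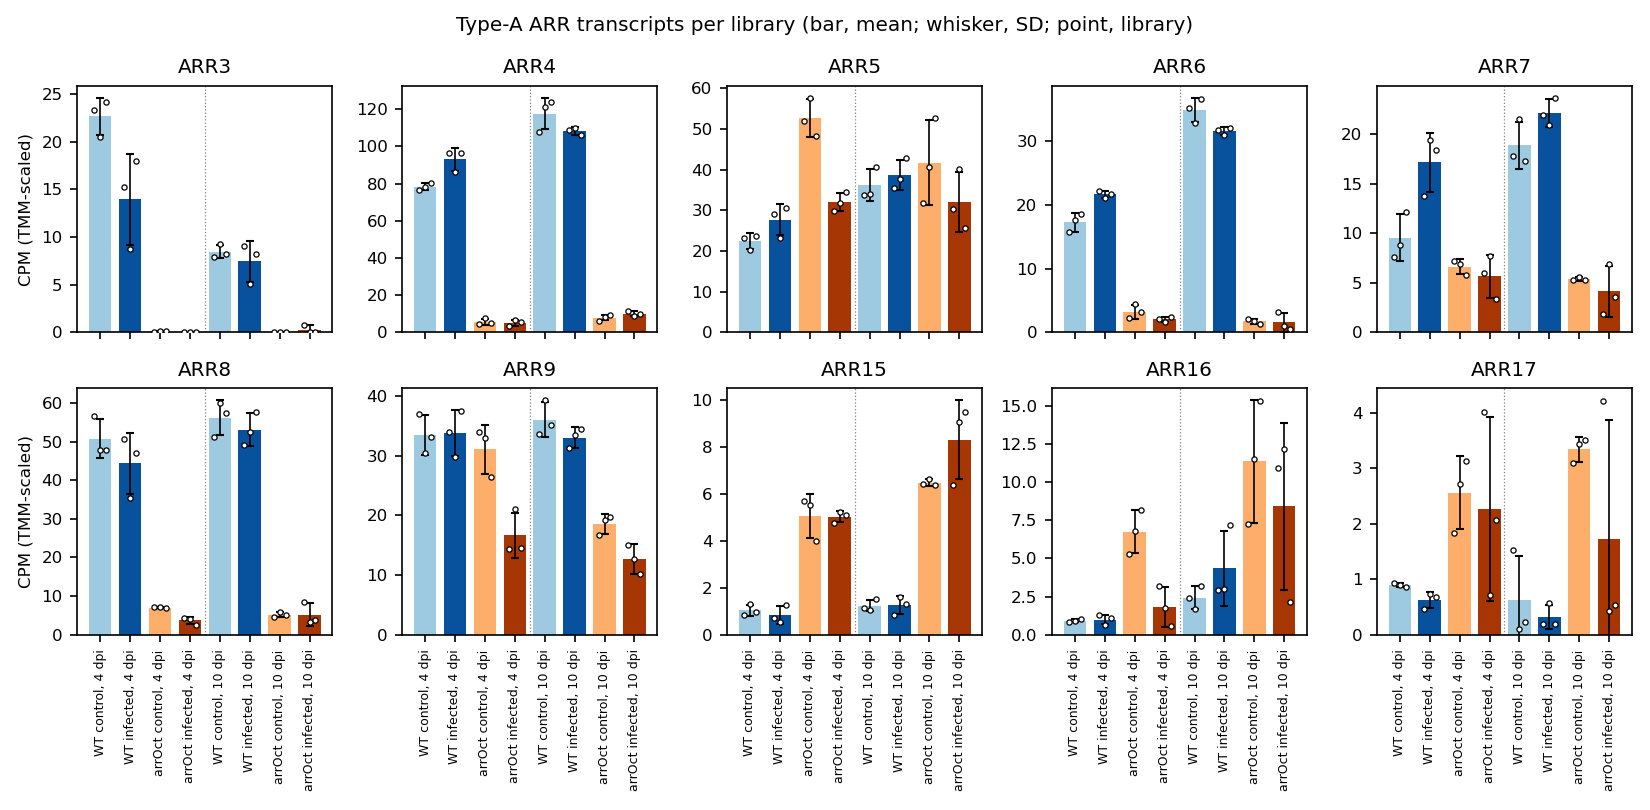
Level of each type-A response regulator gene in each library in CPM, by genotype (arrOct, the mutant), treatment and day; bars are group means, whiskers SDs and points libraries. ARR3, ARR4, ARR6 and ARR8 lie lower in the 12 mutant libraries than in the 12 WT libraries, and ARR15 lies higher.

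In control roots, ARR15 was raised in the mutant by a log2 difference of 2.29 ± 0.30 (SE) at 4 dpi and 2.38 ± 0.26 at 10 dpi. The untargeted ARR16 (AT2G40670) was raised by 2.84 ± 0.44 at 4 dpi (adjusted p = 0.000963), and its difference of 2.23 at 10 dpi missed the threshold (adjusted p = 0.0756). ARR5 transcript was raised by 1.23 ± 0.13 at 4 dpi. ARR7 and ARR9 were lower in control roots at 10 dpi, by a log2 difference of -1.81 ± 0.28 and -0.96 ± 0.14. In infected mutant roots at 4 dpi, ARR5 fell by 0.72, ARR8 by 0.90, ARR9 by 0.90 and ARR16 by 1.85 on the log2 scale relative to control mutant roots. At 10 dpi ARR9 fell by 0.55 in the mutant. In WT roots 0 of the 10 type-A genes passed the threshold for infection in the fit of 12 libraries, and the smallest adjusted p was that of ARR7 at 4 dpi (0.85 ± 0.25, adjusted p = 0.241). The authors' deposited edgeR table for WT infection at 4 dpi lists ARR7 (0.84, adjusted p = 0.0014) and ARR3 (-0.73, adjusted p = 0.0112) as changed. The targeted genes as a list were lower in the mutant at 10 dpi in control roots (median log2 difference -2.63, camera adjusted p = 4.63e-10, 0.0229 with an estimated correlation) and in infected roots (median -2.88, 6.23e-09, 0.0333 with an estimated correlation). These genes carry the lesions that define the mutant, so the list reflects the genotype and is no test of a response. At 4 dpi it did not pass with an estimated correlation in control or infected roots.

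To see how WT roots respond early to the nematode, infected and control WT roots were compared at 4 dpi. Among the genes raised were some of cell wall and inositol metabolism, of jasmonate and tryptophan-derived defence, and of the vascular cambium. The class III peroxidase gene PRX52 (AT5G05340, chromosome 5, 1578951 to 1580875) rose from 0.278 ± 0.161 to 28.4 ± 4.56 CPM, a log2 difference of 6.60 ± 0.40 (adjusted p = 1.54e-05). The myo-inositol oxygenase genes MIOX5 (AT5G56640) and MIOX4 (AT4G26260), which act on the route to cell wall sugars, rose as well. MIOX5 had 0 counts in the control libraries and 12.6 ± 2.91 CPM in infected ones, at least 132-fold higher, with the floor of 3 counts taken over the group. MIOX4 was 59.6-fold higher (95% counting interval 16.1 to 497). The light-harvesting-like gene LIL3:1 (AT4G17600) rose from 2.13 ± 0.766 to 15.8 ± 1.88 CPM, and the pectin methylesterase gene ATPMEPCRB (AT4G02330) from 10.5 ± 0.962 to 44.4 ± 6.96 CPM. Among expansins, which loosen walls, EXPA1 (AT1G69530) rose by a log2 difference of 1.27, EXPA4 by 1.05, EXPA6 by 0.88 and EXPA16 by 3.75.

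Some genes of tryptophan-derived defence moved with these. CYP79B2 and CYP79B3, which turn tryptophan into indole-3-acetaldoxime, rose by 1.23 ± 0.22 and 1.14 ± 0.17 on the log2 scale, and the glucosinolate S-oxygenase gene FMO GS-OX2 by 1.79 ± 0.27. PAD3, the last step of camalexin synthesis, stood at 76.6 ± 19.5 against 23.1 ± 3.52 CPM and missed the threshold (adjusted p = 0.0843). The jasmonate-induced genes VSP1 and TAT3 rose by 1.4 ± 0.18 and 3.85 ± 0.62, and WRKY30, induced by microbial patterns, by 3.94 ± 0.68. The cambium regulators WOX4 and LBD4 rose by 1.0 ± 0.18 and 0.86 ± 0.13. The amino acid permease gene AAP6 rose from 39 ± 4.93 to 93.7 ± 13.4 CPM. Of cytokinin genes, CYP735A2 (AT1G67110), the cytokinin trans-hydroxylase, rose from 6.74 ± 1.64 to 18.4 ± 4.13 CPM. The flavonoid genes CHS and CHI rose by 0.76 and 1.06. The 6 lower genes included the pectin methylesterase gene ATPMEPCRD (-1.1), the clock-linked genes JMJD5 (-1.08) and ELF4 (-0.88), MYR2 (-0.93) and the peptide transporter gene PTR1 (-0.75).

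Of 20190 genes tested at 4 dpi, 83 were higher and 6 lower in infected WT roots, and in all 89 the 3 infected and 3 control libraries did not overlap (18.9% of tested genes did not overlap, and chance gives 10%). Of the 15 genes tested from the list of reported syncytium genes, 3 were higher, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.32e-05, 0.0485 with an estimated correlation). The list of camalexin and indole glucosinolate genes was higher (24 of 24 positive, 2 called, 16 adjusted over the list alone, adjusted p = 8.28e-16, and adjusted p = 0.136 with an estimated correlation). The same held for jasmonate (2 of 23 called, 11 adjusted over the list alone, 5.03e-13, and adjusted p = 0.0899 with an estimated correlation). The hypoxia list had 10 of 10 genes positive, 10 of them past the threshold adjusted over the list alone, with a median log2 difference of 1.1 (3.03e-12, and adjusted p = 0.146 with an estimated correlation). Pattern-triggered immunity (4.27e-08; adjusted p = 0.226 with an estimated correlation), vascular cambium (2.2e-06; 0.136), cell wall loosening (2.32e-05; 0.143), flavonoid synthesis (0.00179; 0.226) and salicylate defence (0.000432; 0.373) were also higher. Cell cycle genes were lower as a list (median -0.14; 6.11e-05, and adjusted p = 0.373 with an estimated correlation). The lists of cytokinin metabolism and cytokinin response each missed the threshold at 0.0916. Markers of shoot photosynthesis moved with these lists, with 26 of 27 positive and a median of 0.59 (3.67e-14; adjusted p = 0.226 with an estimated correlation). With directional fry, cytokinin response passed (adjusted p = 0.0196), and cytokinin metabolism again missed the threshold (0.0948). Pattern-triggered immunity (0.0783), flavonoid synthesis (0.079), photosynthesis markers (0.0948), salicylate defence (0.282) and cell cycle genes (0.337) no longer passed with it. Leaving out control replicate 1, 2 or 3 gave 11, 21 or 18 genes, and leaving out infected replicate 2 or 3 gave 20 or 49. DESeq2 called 328 genes, all 89 among them. Rises made up a smaller share of the calls with voom (436 higher, 199 lower) and without the infected mutant libraries (502 and 119).

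At 10 dpi the question was how the response of WT roots stood at a later stage of feeding. The genes raised again included some of myo-inositol oxygenases and peroxidases and LIL3:1, with some expansin and late anthocyanin genes. MIOX5 had 0 counts in control and 40 ± 22.1 CPM in infected roots, at least 370-fold higher. MIOX1 (AT1G14520) rose from 1.59 ± 0.899 to 24 ± 13.5 CPM, MIOX2 (AT2G19800) from 25.5 ± 3.03 to 83.3 ± 32.8 CPM, and MIOX4 was 123-fold higher (95% counting interval 33.8 to 1020). LIL3:1 rose by 3.2 ± 0.32 on the log2 scale (adjusted p = 0.00174). The peroxidase genes PRX52 and PER4 rose by 5.08 ± 0.68 and 3.87 ± 0.51, SRO4 by 3.13, GSTU12 by 2.75 and the lipid transfer protein gene DIR1 by 2.66. The expansin genes EXPA10 and EXPA16 rose by 2.54 ± 0.43 and 3.96 ± 0.71. DFR, of anthocyanin synthesis, rose by 3.37 ± 0.54, and LDOX was 41.1-fold higher (95% counting interval 6.98 to 1660). IPT1, a cytokinin synthesis gene, rose from 0.24 ± 0.107 to 4.81 ± 1.92 CPM. Genes that fell included the transcription factor genes NF-YA2 (-1.06) and NF-YA10 (-1.19), the sugar transporter gene SWEET16 (-0.88), the triterpenoid genes CYP716A2 (-1.57) and CYP71A16 (-1.41), and MLP328 (-1.06), HWI1 (-0.80) and PRF4 (-0.99).

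Of 20010 genes tested at 10 dpi, 95 were higher and 30 lower, and the groups did not overlap in all 125 (21.4% of tested genes, and chance gives 10%). Of 16 syncytium genes 5 were higher, 8 adjusted over the list alone (camera adjusted p = 1.08e-08, 0.0264 with an estimated correlation). Hypoxia genes were higher as a list (median 0.97; adjusted p = 2.37e-09, and adjusted p = 0.27 with an estimated correlation), with 9 of 10 past the threshold adjusted over the list alone. The control libraries differed among themselves on this list, whose mean log2(CPM + 1) had an SD of 0.664 there and 0.181 in infected roots. PDC1 stood at 855 ± 75.1 against 278 ± 178 CPM (adjusted p = 0.13). The camalexin list (3.15e-05), cell wall loosening (0.000376) and iron deficiency (0.00106) were higher, each with adjusted p = 0.27 with an estimated correlation, and so was flavonoid synthesis (0.00951; 0.351). In the iron list, FRO2 stood at 24.7 ± 9.84 against 6.06 ± 3.89 CPM without passing. Cytokinin response (0.159), cytokinin metabolism (0.328) and jasmonate (0.583) missed the threshold. Shoot photosynthesis markers moved with these lists (26 of 26 positive, 25 adjusted over the list alone, median 0.95; 4.38e-21, and adjusted p = 0.27 with an estimated correlation). Their mean log2(CPM + 1) had an SD of 0.629 among control libraries and 0.0936 among infected ones. Without control replicate 1 or 3 there were 12 genes each, without infected replicate 1, 2 or 3 there were 22, 35 or 57, and DESeq2 called 510.

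**Figure D2:**
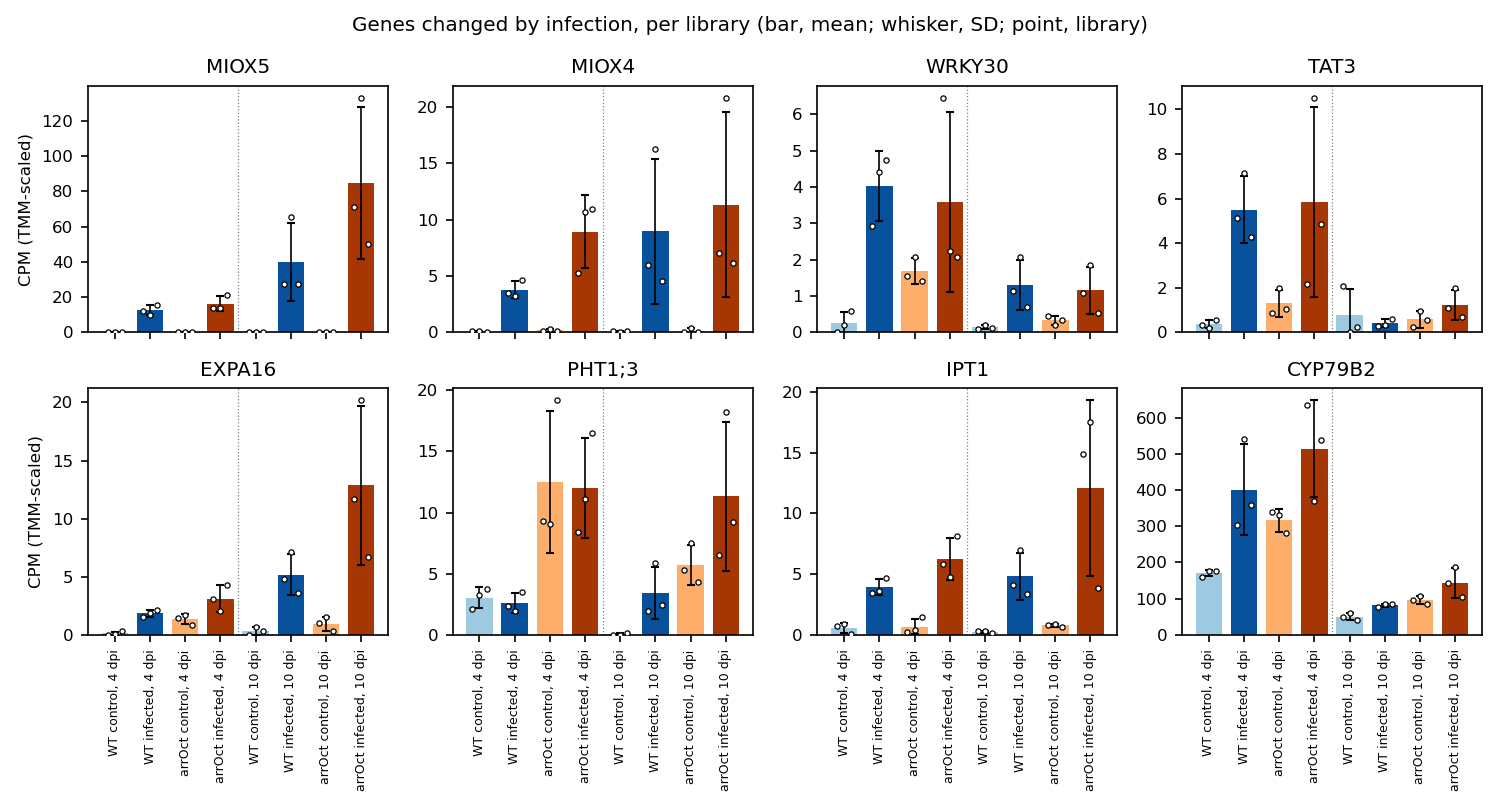
Level of 8 genes changed by infection in each library in CPM, by genotype (arrOct, the mutant), treatment and day; bars are group means, whiskers SDs and points libraries. MIOX5 lies near 0 in control roots and at 12.6 and 40 CPM in infected WT roots at 4 and 10 dpi, while TAT3 is higher in infected than in control WT roots at 4 dpi.

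The change of the infection response between days was tested in WT as the 10 dpi infection difference minus that of 4 dpi. VSP1 had a lower infection difference at 10 dpi by -2.1 ± 0.33 (adjusted p = 0.0431), and JAZ10, at -2.58 ± 0.57, missed the threshold (adjusted p = 0.185). The jasmonate list was lower, with 10 genes lower adjusted over the list alone (median -0.54; camera adjusted p = 7e-11, and adjusted p = 0.112 with an estimated correlation). Genes with lower response at 10 dpi were the triterpenoid gene CYP708A2 (-1.77), scpl31 (-1.84), AT5G38020 (-1.79) and AT3G26460 (-1.53). The phosphate transporter gene PHT1;3 (6.38), FRD3 (1.02), of iron transport, and AT5G42200 (1.64) had a higher response. Cytokinin response (median -0.40; 0.000758, and adjusted p = 0.102 with an estimated correlation) and camalexin genes (median -0.26; 0.00139, and adjusted p = 0.52 with an estimated correlation) were lower, and syncytium genes higher (median 0.34; 0.000514, and adjusted p = 0.112 with an estimated correlation). Of 20117 genes tested, 3 had a higher and 10 a lower response. The count was 0 without 4 dpi control replicate 1 or 3 or infected replicate 2 or 3, 3 without control replicate 2 of 4 dpi or 3 of 10 dpi, 6 and 5 without control or infected replicate 1 of 10 dpi, and 88 with DESeq2. Among 19742 genes tested on both days, 15 were higher on both (82 and 88 higher on each; 0.366 expected for independent lists; one-sided Fisher's exact p = 1.22e-20), and 0 were lower on both (6 and 29; 0.00881 expected).

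**Figure D3:**
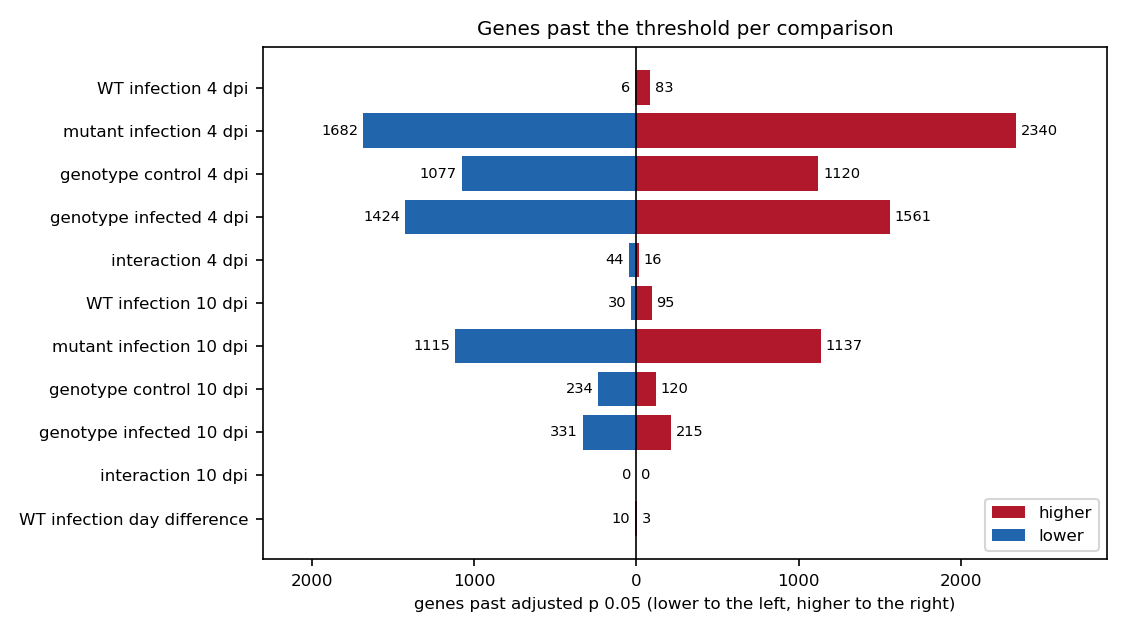
Number of genes past an adjusted p of 0.05 in each comparison (edgeR quasi-likelihood test), with genes lower to the left and higher to the right. The bars of mutant infection hold 4022 and 2252 genes at 4 and 10 dpi, and those of WT infection 89 and 125. All groups of a day shared the estimate of spread in this fit, although infected mutant libraries spread more widely. In fits of the compared libraries alone, mutant infection gave 1453 and 636 genes and WT infection 390 and 370. The size of the contrast between genotypes therefore depended on the fit.

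To see how roots lacking these regulators respond, infected and control mutant roots were compared at 4 dpi. Among the genes raised were PRX52 and MIOX5, which also rose in WT, and low-oxygen, defence and heat shock genes, while SWEET11, SWEET12 and Casparian strip genes fell. PRX52 rose from 0.166 ± 0.0617 to 43.5 ± 15 CPM (adjusted p = 4.14e-06), and MIOX5 was 225-fold higher (95% counting interval 61.9 to 1870). Of low-oxygen genes, ADH1 (AT1G77120) rose by 3.96 ± 0.39 on the log2 scale, PDC1 by 5.17 ± 0.55, PCO2 by 2.51 and HRA1 by 2.44. The sugar exporter genes SWEET11 (AT3G48740) and SWEET12 fell by 2.81 ± 0.28 and 2.49 ± 0.43, and the hexose transporter gene STP1 by 1.14. AAP6 rose by 2.01 ± 0.17. Casparian strip genes fell, with CASP4 at -1.12, CASP1 at -0.92, CASP2 at -0.85 and PER64 at -0.75, while the suberin genes FAR1 and CYP86B1 rose by 0.87 and 0.88. In immunity, PAD3 rose by 2.64 ± 0.36, RBOHD by 1.65 ± 0.21, WRKY33 by 1.41, ICS1 by 1.27 and MPK11 by 2.31, and in jasmonate synthesis AOS by 1.08 and LOX3 by 3.00. The cytokinin receptor genes AHK2 and AHK4 fell by 0.61 and 0.49, the phosphotransfer gene AHP1 by 0.60 and the type-B regulator gene ARR11 by 1.05. BT1 fell by 2.86 ± 0.45, from 282 ± 67.7 to 38.9 ± 22.1 CPM, TIP2;3 fell by 2.4, CYP78A5 by 3.02 and CLE6 by 3.14. Small heat shock genes led the rises and varied between libraries, with HSP17.6A (AT5G12030) going from 1.11 ± 0.261 to a mean of 1010 CPM with an SD of 1240.

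Of 20190 genes, 2340 were higher and 1682 lower (1894 and 2279 with upper-quartile factors), and 3759 of these 4022 had groups that did not overlap (33.3% of tested genes, and chance gives 10%). Hypoxia genes were higher as a list (9 of 10 called, 10 adjusted over the list alone, median 2.47, camera adjusted p = 2.38e-10, and adjusted p = 0.319 with an estimated correlation). So were jasmonate (13 higher and 1 lower of 23, 15 and 1 adjusted over the list alone, 6.06e-06, and adjusted p = 0.319 with an estimated correlation), camalexin (3.15e-05; 0.342), salicylate defence (11 of 19 called, 14 adjusted over the list alone, 3.15e-05; 0.342), pattern-triggered immunity (6.22e-05; 0.342) and suberin (0.00427; 0.425). Lower were the endodermis (5 of 9, 8 adjusted over the list alone, 0.00117; 0.342), sugar and amino acid transport (8 lower, 3 higher of 19; 0.013; 0.319) and cytokinin signalling (4 of 15; 0.0218; 0.319), the last value of each being that with an estimated correlation. Reported syncytium genes went both ways (5 higher, 2 lower of 15; adjusted p = 0.136). Shoot photosynthesis markers moved with them, with 7 of 27 higher (median 0.48; 0.000396, and adjusted p = 0.469 with an estimated correlation). The count was 6451 without infected replicate 3, 2030, 2033 or 2499 without control replicate 1, 2 or 3, and 1453 in a fit of these 6 libraries alone.

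In the mutant at 10 dpi, infection raised PRX52 and several myo-inositol oxygenase genes and lowered several genes of root hairs and the endodermis. LIL3:1 rose from 2.88 ± 0.801 to 74.9 ± 20.6 CPM (log2 difference 4.70 ± 0.34, adjusted p = 3.55e-05), MIOX1 from 2.26 ± 0.0491 to 54.1 ± 18.8 CPM, and MIOX5 was 2350-fold higher (95% counting interval 420 to 92700). MIOX2 rose by 2.29 ± 0.29 and PRX52 by 5.62 ± 0.65. The auxin conjugation gene GH3.3 rose by 5.12 ± 0.96 and the malate transporter gene ALMT1 by 8.46 ± 1.89, with SDs above their means. The camalexin genes CYP71A13, PAD3 and ASA1 rose by 5.89, 1.84 and 1.24. Of salicylate genes, PBS3, CBP60G and WRKY38 rose by 4.05, 1.78 and 1.94, while EDS1 fell by 0.47. The root hair regulator gene RSL4 fell by 1.62 ± 0.30, and the root hair wall genes EXPA7, EXPA18 and PRP3 by 1.45, 1.25 and 1.29. EXT13, an extensin gene, fell from 87.2 ± 12.8 to 20.4 ± 5.54 CPM and the calcium pump gene ACA9 from 25.4 ± 2.82 to 5.6 ± 1.07 CPM. In the endodermis, the receptor kinase gene SGN3 fell by 1.07 ± 0.12, SCR by 0.97 ± 0.14, PER64 by 1.05 and CASP2 by 1.14. AHK4, AHK2, AHP1 and ARR10 fell by 0.55, 0.48, 0.59 and 0.40, and the growth regulator gene GRF3 by 1.13.

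Of 20010 genes, 1137 were higher and 1115 lower (1367 and 902 with upper-quartile factors), and 2216 of these 2252 did not overlap (26.9% of tested genes, and chance gives 10%). As lists, root hair markers (8 of 10 lower, 10 adjusted over the list alone, median -1.27; camera adjusted p = 1.91e-07, and adjusted p = 0.213 with an estimated correlation) and the endodermis (8 of 10 lower, 8 adjusted over the list alone, median -1.06; 2.3e-05, and adjusted p = 0.213 with an estimated correlation) were lower. Cytokinin signalling was lower too (4 of 15, 5 adjusted over the list alone, 0.00247, and adjusted p = 0.213 with an estimated correlation). Camalexin (9 of 24, 13 adjusted over the list alone, 1.43e-05; 0.305), syncytium (8 higher, 2 lower of 16; 0.000104; 0.202) and salicylate genes (4 higher, 2 lower of 17; 0.00356; 0.459) were higher, the last values being adjusted p with an estimated correlation. Shoot photosynthesis markers moved with them, with 14 of 26 higher, 23 adjusted over the list alone (median 0.97; 6.16e-09, and adjusted p = 0.483 with an estimated correlation). The count was 4155 without infected replicate 1, 1443 without infected replicate 2, 1179, 955 or 1176 without control replicate 1, 2 or 3, and 636 in a fit of these 6 libraries alone. Of the genes higher in infected WT roots, 66 of 83 at 4 dpi and 90 of 95 at 10 dpi were also higher in the mutant (9.62 and 5.4 expected for independent lists; one-sided Fisher's exact p = 2.05e-46 and 1.17e-106), and of those lower, 6 of 6 and 19 of 30 (0.5 and 1.67 expected). Of the mutant's calls, 541 higher and 294 lower were shared between days (124 and 92.8 expected).

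To see how the genotypes differ without the nematode, their control roots were compared at 4 dpi. Single genes of cytokinin, iron and nitrate were higher in the mutant, and others of suberin, sulfur and phosphate lower, while of the lists given below only cytokinin response held with an estimated correlation. CYP735A2 (chromosome 1, 25061731 to 25065446) stood at 227 ± 37.9 CPM in the mutant and 6.74 ± 1.64 CPM in WT, a log2 difference of 5.08 ± 0.24 (adjusted p = 1.07e-07). Other cytokinin genes were also higher, the synthesis gene IPT3 by 2.83 ± 0.26, CYP735A1 by 1.52, LBD3 by 1.62, CKX4 by 1.03 and CRF5 by 1.09, while LOG5 was lower at -1.41. Of iron genes, FRO2 stood at 199 ± 57.6 against 36.2 ± 3.25 CPM, and BHLH39, BHLH101 and OPT3 were higher by 1.88, 2.78 and 1.61. The nitrate transporter gene NRT1.1 and the nitrate reductase gene NIA1 were higher by 3.46 ± 0.39 and 3.17 ± 0.43, and the nitrate-induced BT1, BT2 and LBD39 by 5.53, 5.46 and 4.39. NRT2.5, induced by nitrogen starvation, stood at 8.6 ± 12.9 against 466 ± 99.1 CPM, and AMT1;5 and AMT1;3 were lower at -5.04 and -1.05. Of suberin genes, FAR1, FAR4, ABCG20 and KCS2 were lower at -1.58, -1.76, -0.91 and -1.13. SDI1 and LSU1, of sulfur starvation, were lower at -3.86 and -3.30, and the phosphate starvation genes SPX1, MGD3 and RNS1 at -0.95, -2.30 and -3.73. The phosphate transporter gene PHT1;2 was higher at 50.2 ± 3.83 against 2.61 ± 0.637 CPM. The phloem lectin genes PP2-A8 and PP2-A6, LSU2, LSU4 and SADHU1-1 lay at 20.4 to 206 CPM in WT and under 1 CPM in the mutant.

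Of 20190 genes, 1120 were higher and 1077 lower in the mutant, and 2195 of these 2197 did not overlap (36.3% of tested genes, and chance gives 10%). The cytokinin response list was higher (5 of 13 called, 6 adjusted over the list alone, camera adjusted p = 6.94e-05, 0.0488 with an estimated correlation). Iron deficiency was higher (9 of 17, 11 adjusted over the list alone, 3.13e-07, and adjusted p = 0.266 with an estimated correlation). Suberin (9 lower, 1 higher of 13, 11 and 1 adjusted over the list alone, 3.13e-07; 0.298), sulfur (4 of 8, 5 adjusted over the list alone, 3.31e-05; 0.266) and phosphate starvation (4 of 10; 0.011; 0.266) were lower, the last values being adjusted p with an estimated correlation. Nitrogen uptake went both ways (5 higher, 4 lower of 13; adjusted p = 0.833) and cytokinin metabolism likewise (5 higher, 2 lower of 22; 0.439). The count was 1280, 1421 or 1357 without mutant replicate 1, mutant replicate 2 or WT replicate 2, and 4324 in a fit of these 6 libraries alone.

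At 10 dpi fewer genes separated the control roots. CYP735A2 stood at 107 ± 9.55 CPM in the mutant and 27.7 ± 6.53 CPM in WT (log2 difference 1.95 ± 0.37, adjusted p = 0.0157), and LOG2, of cytokinin activation, was higher by 2.07 ± 0.33. CYP79B2 and the indole glucosinolate regulator gene MYB34 were higher by 0.94 and 0.66. Of salicylate genes, FMO1 was lower, at 1.49 ± 0.28 against 25.6 ± 5.44 CPM, WRKY54 lower at -0.78 and EDS1 higher by 0.86. PHT1;2 and QQS were higher by 4.12 ± 0.32 and 3.00 ± 0.28, and LHCB1.1, LHCB1.2, XDH2, LBD26 and GLP6 by 2.29 to 4.18. PP2-A6, PP2-A8, SADHU1-1, LSU2, LSU4 and the resistance gene RPP8 were lower at -4.74 to -9.21. These genes, with FMO1, PHT1;2, QQS, LHCB1.1, LHCB1.2 and XDH2, were among 110 with large differences in each genotype comparison, which clustered on the chromosomes (below). Without genes within 500 kb of those, the count was 16 rather than 354. As lists, sulfur genes were lower (1 of 8 called, LSU2; 6 adjusted over the list alone, camera adjusted p = 5.03e-06, and adjusted p = 0.331 with an estimated correlation). Camalexin genes were higher (0.000495), as were cytokinin response (0.0372), while salicylate genes were lower (0.0212), each with adjusted p = 0.531 with an estimated correlation. Cytokinin metabolism was higher at 0.0372, with adjusted p = 0.287 with an estimated correlation. With a replicate block, cytokinin response (0.0538) and cytokinin metabolism (0.0542) missed the threshold. Of 20010 genes, 120 were higher and 234 lower, and all 354 did not overlap (19.5% of tested genes, and chance gives 10%). Between days 86 higher and 180 lower genes were shared (5.98 and 12.4 expected for independent lists). The count was 226 without mutant replicate 2 and 671 in a fit of these 6 libraries alone.

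Infected roots of the genotypes were compared to ask whether the feeding root differs. At 4 dpi single genes of several groups differed. CYP735A2 stood at 107 ± 18.1 against 18.4 ± 4.13 CPM (log2 difference 2.54 ± 0.21, adjusted p = 1.36e-05). The cytokinin oxidase genes CKX5 and CKX3 were higher by 1.29 and 1.69 and the cytokinin glucosyltransferase gene UGT85A1 by 1.4. The hypoxia genes HB1 and ADH1 were higher by 2.1 ± 0.26 and 2.01 ± 0.36 and the sucrose synthase gene SUS4 by 1.77. OPT3, CYP82C4 and BHLH100 were higher by 1.60, 3.88 and 3.2, and CHI, FLS1 and TT7 by 1.1, 0.91 and 1.64. SWEET11, the phloem sucrose carrier gene SUC2 and AAP2 were lower at -2.06, -0.87 and -1.20, and CASP1, CASP2, CASP4 and PER64 at -0.92 to -1.18. The heat shock factor gene HSFA2 stood at 208 ± 277 against 5.05 ± 2.49 CPM. PP2-A6, PP2-A8, SADHU1-1, LSU2 and the calcium sensor gene CBL2 were lower at -3.75 to -10.16, and ARR4 at -4.20.

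Of 20190 genes, 1561 were higher and 1424 lower (1319 and 1716 with upper-quartile factors), and 2764 of these 2985 did not overlap (27.4% of tested genes, and chance gives 10%). Cytokinin response was higher as a list (6 of 13, 8 adjusted over the list alone, camera adjusted p = 3.28e-05, 0.0367 with an estimated correlation). Iron deficiency (10 of 17, 12 adjusted over the list alone, 2.9e-06; 0.223), hypoxia (7 of 10, 9 adjusted over the list alone, 3.28e-05; 0.403) and flavonoid genes (4 of 5; 0.00695; 0.369) were higher, the last values being adjusted p with an estimated correlation. The endodermis (7 of 9; 0.000281, and adjusted p = 0.369 with an estimated correlation) and sugar and amino acid transport (6 lower, 1 higher of 19; 0.0163, and adjusted p = 0.161 with an estimated correlation) were lower. The count was 4870 or 1918 without mutant replicate 3 or 2, 1659 or 1443 without WT replicate 1 or 3, and 604 in a fit of these 6 libraries alone.

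At 10 dpi infected mutant roots differed from infected WT roots in some indole defence and endodermal genes and in a set of genes near 0 in the mutant. CYP81F4, MYB34, CYP79B2 and CYP71A13 were higher by 0.78, 0.68, 0.82 and 2.98. The receptor-like kinase gene CRK20 stood at 7.18 ± 1.27 against 0.343 ± 0.061 CPM, a log2 difference of 4.34 ± 0.29 (adjusted p = 5.38e-06). PHT1;2, QQS, GLP6, SQS2 and GH3.3 were higher by 3.31, 3.02, 3.36, 3.21 and 4.59. SGN3 and SCR were lower at -0.68 ± 0.12 and -0.72 ± 0.14, and the arabinogalactan protein gene AGP30 at -3.45. PP2-A8 stood at 25.3, 0.283 and 0.936 CPM in mutant replicates 1, 2 and 3 against 186 ± 26.8 CPM in WT, and LSU2 at 21.6, 0.848 and 1.2 CPM against 70.3 ± 17.2 CPM. Camalexin genes were higher as a list (4 of 24 called, 9 adjusted over the list alone, camera adjusted p = 1.22e-07, and adjusted p = 0.214 with an estimated correlation), and the ABA and cold list as well (median 0.50; 0.00258, and adjusted p = 0.214 with an estimated correlation). The endodermis (2 of 10; 6.33e-05; 0.214), root hair markers (median -0.52; 0.000162; 0.412) and sulfur genes (1 of 8, LSU2; 0.00117; 0.429) were lower, the last values being adjusted p with an estimated correlation. Of 20010 genes, 215 were higher and 331 lower (265 and 279 with upper-quartile factors), and 544 of these 546 did not overlap (16.9% of tested genes, and chance gives 10%). The count was 1292 without mutant replicate 1, 271 or 274 without WT replicate 1 or 3, and 203 in a fit of these 6 libraries alone.

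Many genotype differences were large and present whatever the treatment and day. Of 19742 genes tested in the 4 genotype comparisons, 110 passed the threshold with an absolute log2 difference above 2 in 1 direction in each of them, 33 higher and 77 lower in the mutant. They included ARR3, ARR4, ARR6, ARR8 and ARR15, and PP2-A6, PP2-A8, LSU2, SADHU1-1 and RPP8. FMO1, LSU4, PHT1;2, QQS, LHCB1.1, LHCB1.2, XDH2, CRK20, SQS2, AGP30 and CBL2, named above, were among them as well. The 110 were unevenly placed, with 31 on chromosome 1, 18 on chromosome 2, 7 on chromosome 3, 11 on chromosome 4 and 43 on chromosome 5, where 12 lay between 18 and 19 Mb. Of the 110, 96 had another within 500 kb, against 51 to 87 in 1000 random draws of as many tested genes. In control roots at 10 dpi, 297 of 354 called genes (83.9%) lay within 500 kb of 1 of the 110, against 30.8% of tested genes. The share was 63.4% in infected roots at 10 dpi, and 40.6% and 37.2% in control and infected roots at 4 dpi (30.6% of tested genes). The 110 were themselves counted as near and were called in each comparison by choice, which raises these shares. Because the 110 were chosen on these libraries, segments were also drawn from 1 day and tested on calls of the other. Segments from 4 dpi held 202 of 229 further calls of control roots at 10 dpi (88.2% against 57.8% of tested genes; one-sided Fisher's exact p = 4.71e-24). Segments from 10 dpi held 836 of 2078 further calls at 4 dpi, a smaller excess (40.2% against 33% of tested genes, one-sided Fisher's exact p = 1.43e-13). Of the 8 targeted genes, ARR4 and ARR7 had 1 and 8 of the other genes of the 110 within 2 Mb, and the other 6 had 0. In 11 of the 12 mutant libraries the 77 lower genes had a median of 0.129 to 1.64% of the WT group mean of the same treatment and day. In infected mutant replicate 1 at 10 dpi that median was 10.3%.

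**Figure D4:**
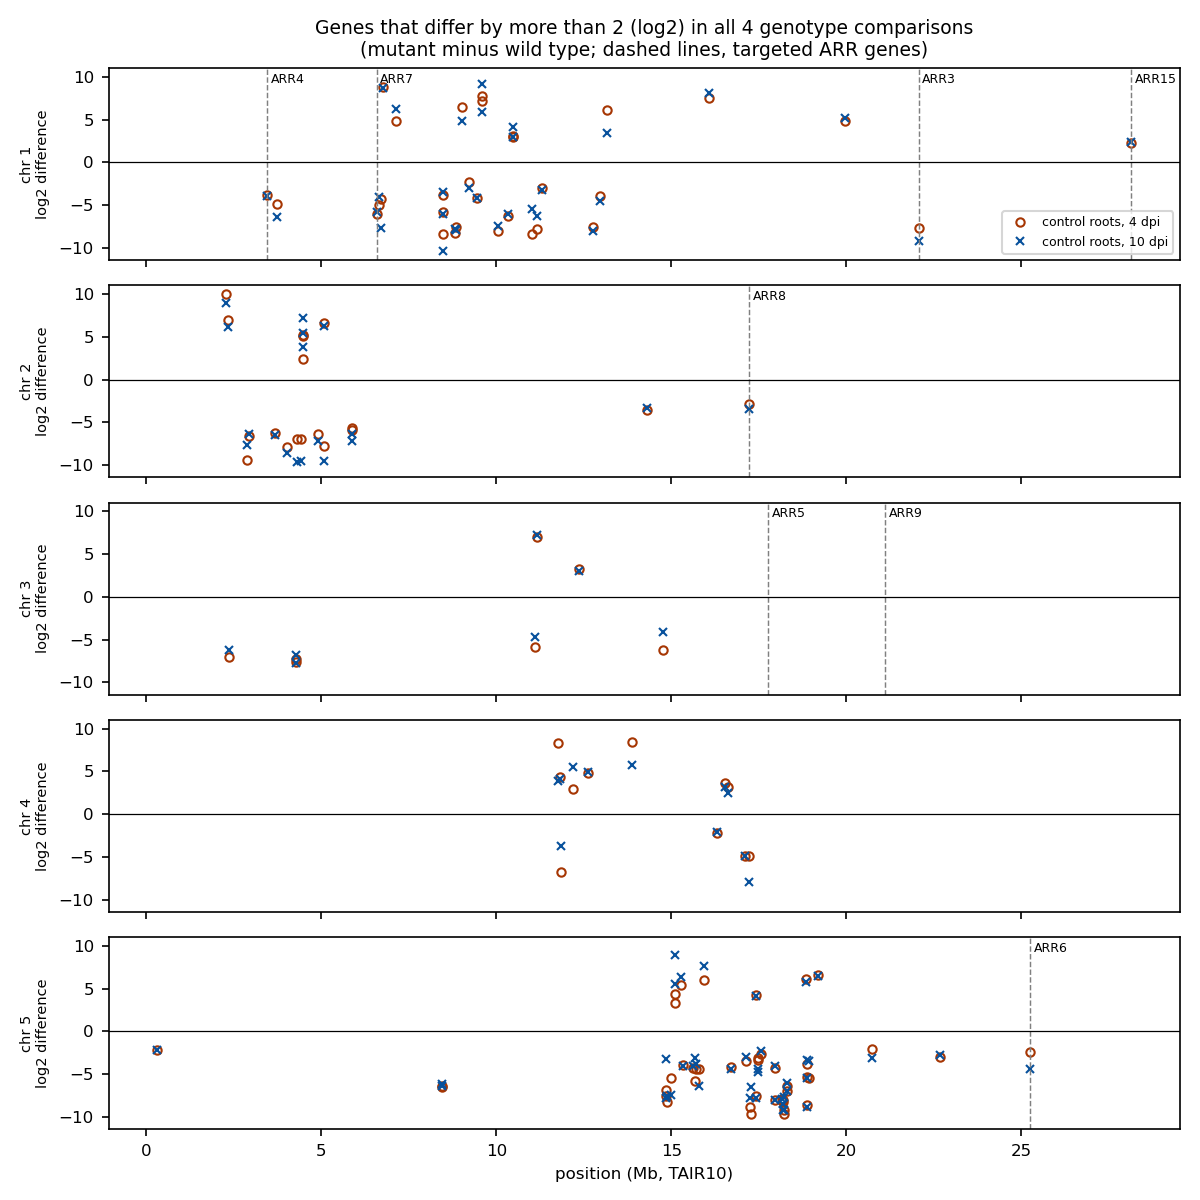
Log2 difference (mutant minus WT) of the 110 genes with large differences in each genotype comparison, in control roots at 4 dpi (circles) and 10 dpi (crosses), against position in Mb (TAIR10) on each chromosome; dashed lines mark the targeted ARR genes. The genes lie unevenly, with 43 on chromosome 5.

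Whether the genotypes respond differently to infection was tested as the interaction, the infection difference in the mutant minus that in WT. At 4 dpi the cytokinin gene CYP735A2 responded in opposite directions: it rose in WT and was lower in infected than in control mutant roots, with an interaction of -2.53 ± 0.30 (adjusted p = 0.00776). Reads of ARR5, itself a targeted gene, also had a lower response in the mutant, at -1.02 ± 0.18 (adjusted p = 0.0401). The fermentation gene ADH1 had a higher response, at 2.85 ± 0.50 (adjusted p = 0.0454), while PDC1 at 3.58 ± 0.67 missed the threshold (adjusted p = 0.0608). The light stress gene ELIP2 (4.65), AT5G10040 (5.99), AT5G07330 (4.37) and AT4G33905 (4.41) had a higher response, and AT3G05770 (-3.30), AT2G43550 (-2.0), AT5G28145 (-3.14) and AT4G14250 (-3.03) a lower one. As lists, hypoxia had a higher response (1 of 10 called, 7 adjusted over the list alone, median 1.36; camera adjusted p = 1.62e-06, and adjusted p = 0.623 with an estimated correlation). Suberin was higher (5 adjusted over the list alone, median 0.66; 0.00125, and adjusted p = 0.672 with an estimated correlation). Sugar and amino acid transport was lower (8 lower, 1 higher adjusted over the list alone, median -0.31; 0.00221, and adjusted p = 0.121 with an estimated correlation), with SWEET11 at -1.98 ± 0.37 missing the threshold (adjusted p = 0.0522). Of 20190 genes, 16 had a higher and 44 a lower response in the mutant. This balance was not stable, with 299 higher and 346 lower in DESeq2, 137 and 104 in a fit of all 24 libraries, 500 and 348 in voom and 1061 and 679 without infected mutant replicate 3. The count was 1740 in the last of these. It was 6, 5 or 24 without control mutant replicate 1, 2 or 3, 6, 8 or 14 without control WT replicate 1, 2 or 3, and 34, 18 or 11 without infected WT replicate 1, 2 or 3. A replicate block gave 24 genes, DESeq2 645 and a fit of all 24 libraries 241.

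At 10 dpi root hair and endodermal genes had the lowest interactions as lists. EXPA7 (-1.32 ± 0.32, adjusted p = 0.347), IRE (-1.29), EXPA18 (-1.04) and PRP3 (-1.01) among root hair genes, and SGN3 (-0.74 ± 0.17, adjusted p = 0.284) and SCR (-0.70) in the endodermis, did not pass the threshold. The root hair list was lower (10 of 10 negative, 6 adjusted over the list alone, median -1.02; camera adjusted p = 5.5e-08, and adjusted p = 0.336 with an estimated correlation). The endodermis was lower too (2 adjusted over the list alone, median -0.65; 0.000647, and adjusted p = 0.395 with an estimated correlation). Jasmonate genes were higher (median 0.40; 0.000647, and adjusted p = 0.395 with an estimated correlation), with JAZ10 at 2.41 ± 0.63 and LOX4 at 1.60 ± 0.62. The ABA and cold list was higher (median 0.54; 0.000721, and adjusted p = 0.336 with an estimated correlation), with LTI30 at 0.85 ± 0.19 and COR15A at 1.43 ± 0.61. Of 20010 genes edgeR called 0 at an adjusted p of 0.05 and 1550 at an unadjusted one, DESeq2 called 89 and limma's voom with library quality weights 191. Without mutant infected replicate 1 edgeR called 367 genes, and without replicate 3 it called 1.

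**Figure D5:**
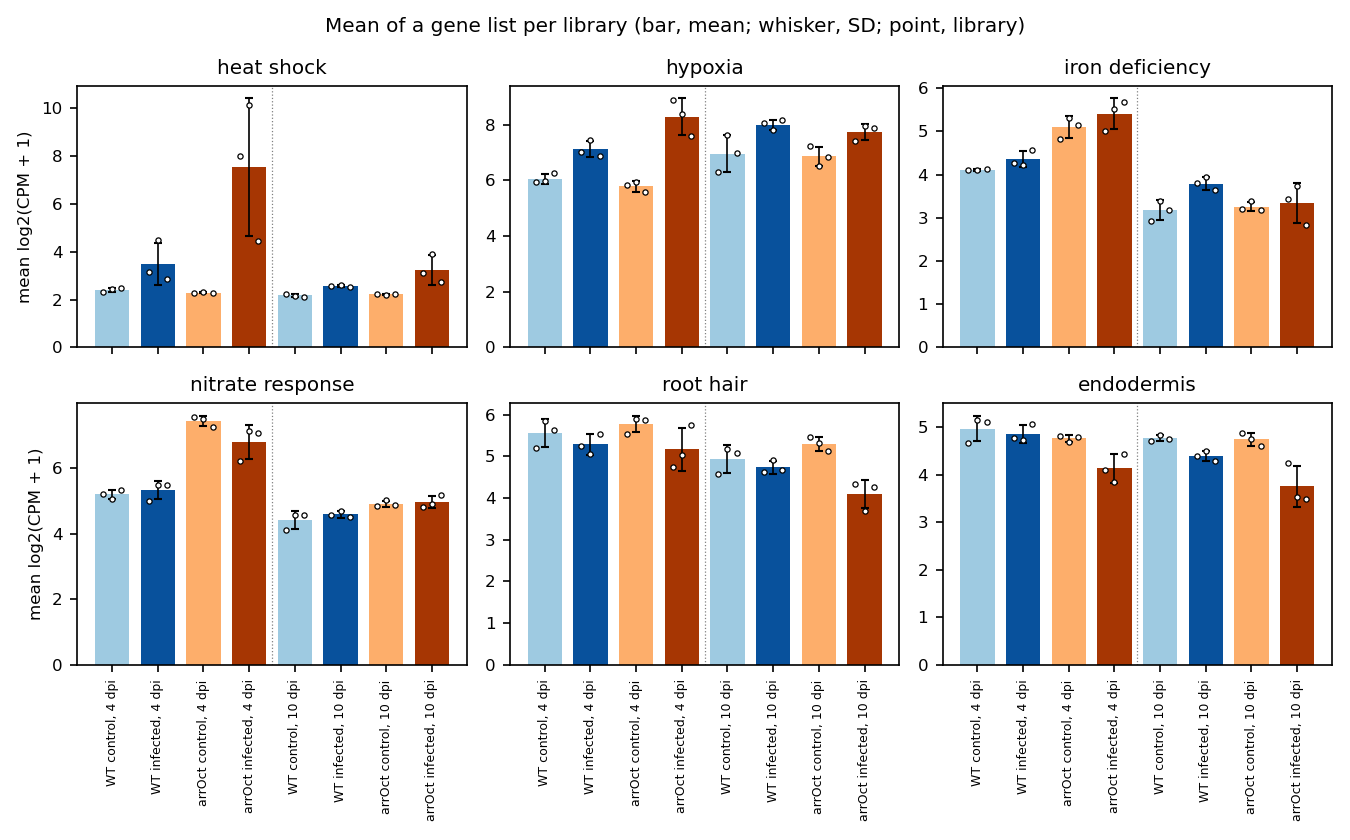
Mean log2(CPM + 1) of 6 gene lists in each library, by genotype (arrOct, the mutant), treatment and day; bars are group means, whiskers SDs and points libraries. The heat shock list spreads most widely in infected mutant roots at 4 dpi, with an SD of 2.87.

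Differences between the genotypes were also set beside infection of WT, gene by gene. They are whole differences of the mutant from WT and were not traced to the regulators. The genotype difference in control roots and the WT infection difference at 4 dpi correlated across genes with r = 0.177, and genes are not independent replicates. Both share the WT control libraries, which gave r = 0.496 and a covariance of 0.036 in 20 simulations with no effect. The observed covariance was 0.0626, a difference of 0.0266, and part of any excess of shared calls may come from the shared controls. Of the calls, 33 genes were higher in both (4.6 expected for independent lists), CYP735A2 among them, 3 lower in both and 4 opposite. Without shared libraries, the 4 dpi genotype difference against the 10 dpi infection difference gave a covariance of 0.0586, with 17 genes higher and 17 lower in both (4.65 and 1.56 expected). At 10 dpi the covariance was 0.0395 against 0.0334 simulated. The 10 dpi genotype difference against the 4 dpi infection difference gave -0.00883.

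The authors' deposited tables list genes of 6 comparisons. In the authors' deposited table for WT infection, 1239 genes are listed at 4 dpi and 1311 at 10 dpi, and it holds all 89 and all 125 genes called here. In the authors' deposited table for control roots, 4822 and 1129 genes are listed, with 2197 of the 2197 and 351 of the 354 called here. In the authors' deposited table for infected roots, 1831 and 733 genes are listed, with 1503 of the 2985 and 425 of the 546 called here. Of the calls in fits of the compared libraries alone, it holds 580 of 604 at 4 dpi and 202 of 203 at 10 dpi. The log2 difference of PRX52 at 4 dpi is 6.62 in the authors' deposited table.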

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

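Chosen after the result was seen were the heat shock list, the tests of 1 library apart, of unequal heat exposure and of a mutant response for that list, and both tests of the reads in infected mutant replicate 1 at 10 dpi.

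The response to infection differed between genotypes at 4 dpi, by a test of the interaction itself, in 60 genes. The cytokinin gene CYP735A2 and the fermentation gene ADH1 were among them. So was ARR5, itself a targeted gene, whose reads do not test whether it works. CYP735A2 had a lower response in the mutant by -2.53, and AT3G05770 by -3.30, AT2G43550 by -2.0, AT5G28145 by -3.14 and AT4G14250 by -3.03 on the log2 scale. ADH1 had a higher response by 2.85, AT5G10040 by 5.99, AT5G07330 by 4.37, ELIP2 by 4.65 and AT4G33905 by 4.41. Of lists, hypoxia had a higher median response by 1.36 and suberin by 0.66, and sugar and amino acid transport a lower one by -0.31, and these calls ended with an estimated correlation (adjusted p = 0.623, 0.672 and 0.121). Of 100 splits of the libraries, 7 gave as many genes as the real one (60; highest other 3300), so chance was not excluded. Nor was the balance of 16 higher and 44 lower stable, at 1061 and 679 without infected mutant replicate 3. The split with 3300 swapped whole pairs of groups and so tested the sum of both genotypes' infection effects, which is a structure of the samples. Splits exchanged infected and control libraries within a genotype. They did not keep the infection effect that the genotypes share, and so cannot test the interaction alone.

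At 10 dpi the same test called 8 lists and 0 single genes, and 0 lists with an estimated correlation. Root hair genes had a lower median response in the mutant by -1.02 and endodermis genes by -0.65, while jasmonate genes had a higher one by 0.40 and ABA and cold genes by 0.54 (adjusted p = 0.336, 0.395, 0.395 and 0.336 with an estimated correlation). With edgeR 0 genes passed (1550 at an unadjusted p of 0.05; DESeq2 89, voom 191), and with a real count of 0 all 100 of 100 splits give as many whatever the data. The highest other split, with 2870 genes, was the swap of whole pairs of groups, and the highest without it gave 315.

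The WT response to infection differed between days, by a test of that difference, in 13 genes. Genes with a lower response at 10 dpi were VSP1, of jasmonate response, at -2.10, CYP708A2 at -1.77, scpl31 at -1.84, AT5G38020 at -1.79 and AT3G26460 at -1.53. PHT1;3, at 6.38, FRD3, at 1.02, and AT5G42200, at 1.64, had a higher one. As list medians, jasmonate stood at -0.54, cytokinin response at -0.40, the reported syncytium genes at 0.34 and camalexin genes at -0.26 (adjusted p = 0.112, 0.102, 0.112 and 0.52 with an estimated correlation). As many genes came from 2 of 100 splits, the real one included. The splits exchanged infected and control libraries within a day, so they did not keep the infection effect that the days share. They therefore cannot decide whether a difference between days came by chance, and the number was not stable. It was 0 in a fit of all 24 libraries and 0 without any 1 of 4 libraries of 4 dpi, and 7 with median-ratio factors. The highest other split, with 1724 genes, was again a swap of whole pairs of groups.

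Heat shock genes rose in infected mutant roots at 4 dpi, with 20 of 20 called higher and a median log2 difference of 6.78. In 11 of the 20 all 3 libraries lay above every other library of the day, the median in infected WT roots was 1.35 with 0 called, and at 10 dpi 5 genes were called higher in the mutant. The value argues against 1 library apart from its group, since without replicate 2, which held the most heat shock reads, 20 still passed, and against library depth, since 20 passed after thinning to the smallest library. Heat exposure that differed between samples may be a source. The list mean had an SD of 2.87 among the infected mutant libraries, against at most 0.879, in infected WT roots, in the other groups of the day. An uneven response to infection would spread the list mean as well, so the SD cannot tell these apart. A response of the mutant to infection stays open, because the median interaction was 5.57 while 0 of the 20 genes passed with edgeR (11 adjusted over the list alone).

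Infected mutant replicate 1 at 10 dpi held reads of genes that were near 0 in the other mutant libraries. The 77 genes lower in the mutant in every genotype comparison had a median there of 10.3% of the infected WT mean, against 0.129 to 1.64% in the other mutant libraries. RNA of WT roots in that library is a candidate explanation, which predicts a like share on every chromosome. The medians of chromosomes with at least 5 of these genes lay within a factor of 1.13 of the overall one. Targeted genes lower in the mutant went both ways. ARR3, ARR6 and ARR8 stood at 0.815, 3.26 and 8.56 CPM there, above the other infected mutant libraries of the day. ARR4 (11.3 against 9.05 and 10 CPM) and ARR9 were little higher, and ARR7 was lowest (1.9 against 6.93 and 3.61 CPM). An infection effect shared by the infected libraries was not seen in the other 2 of the day, at 0.554 and 1.46% beside 0.204 to 1.42% in mutant controls. The 95% intervals of their medians over the genes reached at most 3.15%, and that of replicate 1 spanned 8.04 to 11.5%. The pattern was noticed as replicate 1 against the other mutant libraries, so these values restate it more than they test it. An infection effect confined to that sample was not tested. Without that library 4155 genes were called for infection of the mutant, 1292 for genotype in infected roots and 367 for the interaction.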

How the results depend on the processing

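Chosen after the data were seen were voom with library quality weights, fits without the infected mutant libraries, leaving out genes near shared large genotype differences, and thinning. Where a value changed, the cause was not tested unless given.

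Of 527 named gene results, 323 passed the threshold, and 191 of those passed under every alternative run for them. Over 7815 alternative values, 6987 kept their direction and side of the threshold, 621 fell short of it, 166 newly passed it and 41, in 19 type-A ARR or flavonoid results not past the threshold, changed sign.

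In WT infection at 4 dpi (89 genes) a replicate block gave 51, DESeq2 328, voom 635, a fit of the compared libraries 390 and a fit without infected mutant libraries 621, with 89, 89, 88 and 88 of the genes shared in the last 4. At 10 dpi (125) DESeq2 gave 510, voom 916, the compared libraries 370, the fit without infected mutants 633 and all 24 libraries 250. Mutant infection fell to 1453 of 4022 at 4 dpi and 636 of 2252 at 10 dpi in the compared libraries alone. The contrast with WT infection was smaller there, at 1453 against 390 genes at 4 dpi and 636 against 370 at 10 dpi. In the main fit, which pooled the spread of all groups of a day, it was 4022 against 89 and 2252 against 125. The genotype difference in control roots moved from 2197 to 5615 with voom, 4324 in the compared libraries and 3891 without infected mutants at 4 dpi, and from 354 to 918, 671 and 711 at 10 dpi. In infected roots the compared libraries gave 604 (of 2985) at 4 dpi and 203 (of 546) at 10 dpi, where DESeq2 gave 908. Without genes near shared large differences, which tests fewer genes, the counts were 1239 and 16 in control roots at 4 and 10 dpi and 1766 and 84 in infected roots. The interaction at 4 dpi (60) was 127 with upper-quartile factors, 24 with a replicate block, 645 with DESeq2, 848 with voom, 241 with all 24 libraries and 38 after thinning. At 10 dpi (0) it was 1 with upper-quartile factors, 1 with no filter on low counts, 1 with all 24 libraries, 89 with DESeq2 and 191 with voom. The difference between days (13) was 7 with median-ratio factors, 88 with DESeq2, 21 with voom and 0 with all 24 libraries (edgeR; 1325 at an unadjusted p of 0.05 in the fit of 12). Upper-quartile factors shifted the split of directions as given with the counts. In WT infection at 10 dpi (95 higher, 30 lower) the split was 542 and 374 with voom, 240 and 130 in the compared libraries and 382 and 251 without infected mutants. For genotype in infected roots at 4 dpi (1561 and 1424) it was 247 and 357 in the compared libraries.

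Leaving out 1 library at a time gave 11 to 64 genes for WT infection at 4 dpi, 12 to 180 at 10 dpi, 2030 to 6451 and 955 to 4155 for mutant infection, 1280 to 1796 and 226 to 294 for genotype in control roots, 1443 to 4870 and 271 to 1292 in infected roots, 5 to 1740 and 0 to 367 for the interaction, and 0 to 19 for the difference between days. Most of the libraries behind these moves are named with the counts above. Infected mutant replicate 3 at 4 dpi and replicate 1 at 10 dpi, with quality weights of 0.195 and 0.161, gave the highest counts when left out of the mutant's comparisons.

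Lists past the threshold depended most on the correlation. With an estimated one, WT infection at 4 dpi went from 18 to 1, mutant infection from 20 to 0, genotype in control and infected roots from 13 and 11 to 1 each and the interaction from 8 to 0. At 10 dpi these went from 13 to 1, 14 to 0, 12 to 1, 9 to 1 and 8 to 0, and the difference between days from 15 to 0. The 1 list kept for genotype was cytokinin response at 4 dpi and, at 10 dpi, that of the targeted genes themselves. Directional fry gave 7 for WT infection and 1 for the interaction at 4 dpi, and 1, 7, 2, 5 and 0 at 10 dpi in the same order, and 5 for the difference between days. Mixed fry gave 26 for genotype in control and 26 in infected roots at 4 dpi, 24 for mutant infection, 6 and 15 for genotype and 1 for the interaction at 10 dpi, and 4 for the difference between days. The overlap of WT infection between days was 4 genes at an adjusted p of 0.01 (15 at 0.05). The covariance of the mutant effect at 10 dpi with the infection effect was 0.0395, and -0.00883 with that of the other day.

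Signs changed in values close to 0 or at low counts. For WT infection at 4 dpi, ARR9 (0.0075) was -0.0030 with median-ratio factors, -0.0069 with no filter, -0.0039 with DESeq2, -0.0079 in the compared libraries and -0.0039 with all 24 libraries, and -0.0751 to 0.095 with 1 library left out. Over the left-out libraries TT7 ranged from -0.32 to 0.97 and ARR16 from -0.12 to 0.33 there. In mutant infection at 4 dpi, ARR15 ranged from -0.17 to 0.080, ARR4 from -0.38 to 0.091, ARR17 from -0.90 to 0.26 and ARR7 from -0.50 to 0.042. ARR9 ranged from -0.18 to 0.0053 for genotype in control roots and ARR17 from -0.38 to 0.80 for the interaction. In WT infection at 10 dpi, ARR15 was -0.0083 with a replicate block and ranged from -0.19 to 0.24, ARR17 from -1.66 to 0.82 and ARR3 from -0.35 to 0.036. In mutant infection at 10 dpi, ARR6 ranged from -1.15 to 0.32, ARR8 from -0.51 to 0.26 and ARR16 from -0.80 to 0.022. For the interaction at 10 dpi, ARR17 was -0.40 with a replicate block and ranged from -1.78 to 0.71, ARR8 from -0.43 to 0.34 and ARR6 from -1.01 to 0.47. For the difference between days ARR8 ranged from -0.012 to 0.24.

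Replicate numbers did not clearly pair the libraries. After group means were removed, 11 of 36 matches at 4 dpi and 14 of 36 at 10 dpi were best with the own number. Each match had 3 libraries of another group to choose from. A batch shared by replicate number is not excluded by these counts. Small changes are partly missed: on simulated data 51% of genes changed by a log2 of 1 were recovered in WT infection at 4 dpi.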

Other observations

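Chosen after the result was seen were the nitrate list, the test of a strain variant and that of regulators acting wherever the genes lie, and the test of the genotype difference between days.

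Among groups not described above, markers of the phloem were lower in infected mutant roots at 4 dpi, with 5 of 10 genes past the threshold (camera adjusted p = 0.00466, 0.342 with an estimated correlation). Xylem markers were lower in the same comparison, with 4 of 14 (0.00427, and 0.362 with an estimated correlation), and in infected WT roots at 4 dpi as a list (median -0.26; 0.0019, and 0.341 with an estimated correlation). Root tip markers were lower in infected mutant roots at 10 dpi, with 2 of 6 past the threshold and a median of -1.19 (0.00115, and 0.459 with an estimated correlation). Phenylpropanoid and lignin genes were higher in infected mutant roots at 4 dpi (6 of 14; 0.00344, and 0.425 with an estimated correlation) and lower in control mutant roots than in WT at that day (4 lower, 1 higher; 0.00172, and 0.74 with an estimated correlation).

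Ethylene genes were higher in infected mutant roots at 4 dpi (7 higher, 1 lower of 21; 0.00427, and 0.425 with an estimated correlation) and in infected WT roots at 4 dpi as a list (0.00232, and 0.373 with an estimated correlation). Auxin genes were mixed, with 6 higher and 1 lower of 22 in infected mutant roots at 4 dpi (0.0626). Clock genes were lower as a list in infected WT roots at 4 dpi, with 1 of 13 called (0.0212, and 0.373 with an estimated correlation), and had 5 higher and 3 lower in infected mutant roots at that day (0.558).

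Some iron and nitrate genes differed between genotypes at 4 dpi. As a list, the iron genes did not hold with an estimated correlation in control or infected roots, as given above. In control roots the median log2 difference was 1.61 over all iron genes and 2.21 over all nitrate genes at 4 dpi, and -0.03 and 0.41 at 10 dpi, where 0 were called. At 4 dpi 26 members were called higher in the mutant, and 24 of them after thinning to the smallest library. The genotype difference of control roots changed between days in 1313 of 20057 genes, 680 higher and 633 lower at 10 dpi, with 5 iron genes (camera p = 3.22e-06, 0.0425 with an estimated correlation) and 14 nitrate genes among the lower. The nitrate genes were listed because such genes were seen to differ in these libraries, so their number is no test. In infected roots 18 of 20 nitrate genes were higher in the mutant at 4 dpi.

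The 110 genes with large genotype differences in each of 4 comparisons lay closer together than random tested genes. Of them 96 had another within 500 kb, against 51 to 87 in 1000 draws (permutation p = 0.001, the smallest these draws can give), so segments from another strain are a candidate explanation, although 6 of the 8 targeted genes had 0 of the other genes within 2 Mb. Tandem copies that share reads are argued against as the whole source: after merging genes within 10 positions of each other, 47 of 68 still had another near, above the bound of 42 set on random draws, though within their full range (19 to 48). If the missing regulators acted on these genes wherever they lie, the genes would be placed like random ones. Instead 87.3% had another near, against 46.4 to 79.1% in draws. This share counts tandem neighbours, and regulators acting on genes that lie together would raise it too. It therefore argues only against placing like random genes and cannot decide on the regulators. An effect of the regulators on single genes of the 110 stays open, as it was not tested.

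Of comparisons of a pair of groups, each with 10 splits of its 6 libraries, the real split gave the most genes in all 8. These splits are too few for a share under 0.05. The real count and the highest other were 89 and 0 for WT infection at 4 dpi, 125 and 0 at 10 dpi, 4022 and 1 for mutant infection at 4 dpi, and 2252 and 0 at 10 dpi. For genotype they were 2197 and 0 in control roots at 4 dpi, 354 and 0 at 10 dpi, 2985 and 120 in infected roots at 4 dpi, and 546 and 37 at 10 dpi. In each, 1 split of the 10, the real one, gave as many.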
